A study of Mus musculus with 6 samples.

How the data were processed

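Gene expression was measured by RNA sequencing in 6 libraries of mouse thymocytes, the developing T cells of the thymus. The cells were double negative 3 (DN3) cells, a stage that lacks CD4, CD8 and CD44 and carries CD25, from adult mice of 6 to 8 weeks on a mixed C57BL/6 and 129 background. Per the labels' protocols, cells were processed directly after removal without culture, lysed in Trizol, and total RNA was isolated. The 3 WT libraries came from mice with a floxed Rpl22l1 gene and no Cre recombinase, and the 3 L1 KO libraries from mice that carried Cre, which removes the floxed part. The series text pairs Cre and genotype the other way round; the labels of the samples were followed, and the Rpl22l1 level in each library is reported as a check of them.

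The authors deposited 1 table of raw read counts per gene symbol, with 34573 genes, 2 header lines and 5 summary rows of the counting tool. The submitters' processing notes name TopHat2, HTSeq and the GRCm38 mouse assembly; versions, the gene annotation, the strand setting and filters are not given in the sources used here. Because the strand setting is unknown, reads of overlapping or antisense genes could not be told apart. Column names with Ctrl were matched to the WT titles by number, Ctrl being the only group besides KO, and 0 columns were left unmatched. The summary rows were kept out of library sizes and tests. Reads that the counting tool assigned to no feature made up 50.4% to 51.9% of all rows, more than the 37.7% to 39.7% counted to genes, in all 6 libraries. As the annotation and strand setting are unknown, these may include reads that lie within annotated genes. Multiply aligned reads made up 9.14% to 10.2%, and ambiguous reads 0.498% to 0.520%.

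Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 13729 genes. Libraries were scaled by TMM, dispersions were estimated with estimateDisp, and groups were compared with glmQLFit (robust) and the two-sided quasi-likelihood F test. P-values were adjusted by the Benjamini-Hochberg method at 0.05. Levels are TMM-normalised CPM, counts scaled to library size, as mean ± SD of 3 libraries. The standard error (SE) of a log2 fold change is the one implied by the F statistic. Nothing in the labels says whether the 3 libraries of a group came from separate mice, so p-values measure only the spread between these samples, which may be technical. Read counts without molecular identifiers are not independent molecules, and intervals and floors cover counting error only.

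Before the data were examined, 18 lists of genes for pathways and T cell stages and 8 lists of markers of other cell types were fixed. Lists with at least 5 tested genes were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the 26 lists. Camera with an estimated correlation and fry were run beside it. The estimated-correlation version rests on the few residual degrees of freedom of 6 libraries, and the smallest adjusted p it gave any list was 0.38. For apoptosis regulators the estimated correlation was −0.00173, under the preset 0.01, yet the adjusted p went from 0.00888 to 0.418. A loss under this version therefore does not by itself show that correlation between genes explains a call. It does not exclude this either, as other lists had estimated correlations far above the preset. These were 0.809 for G2/M and mitosis, 0.792 and 0.798 for large and small ribosomal proteins, 0.651 for G1/S and DNA replication and 0.52 for oxidative phosphorylation. For such lists the camera p at the preset correlation may be much too small. Listed symbols missing from the table were matched through the synonyms of the reference's gene table. The rule for named genes was also fixed: Rpl22l1 and Rpl22; the 10 largest rises and 10 largest falls among genes past the threshold with non-overlapping groups, at least 5 CPM in the higher group and a symbol that is not a predicted or pseudogene name; the 4 members with the smallest p of each list; and Trp53, Smad1, Smad2 and Hoxa9, of which Hoxa9 did not pass the count filter. One gene that the rule names is not reported here. Genes outside the rule are said to be chosen after their values were seen. Coordinates are from the GENCODE annotation of GRCm38, matched by symbol for 94.9% of the tested genes.

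The titles give both groups the numbers 1 to 3. Deviations from the group means correlated between same-numbered libraries at 0.58, 0.17 and 0.34, all above the threshold of 0.1 set for treating numbers as pairs. However, WT 2 correlated better with KO 3, at 0.29, than with KO 2, and KO 2 better with WT 3, at 0.22, than with WT 2, so that mainly number 1 stood apart. The labels state no litter, batch or day behind the numbers. By the numerical rule the numbers count as pairs. The main values nevertheless come from the fit on group alone, as the labels do not say what the numbers mark, and the block is an alternative. The correlations were first seen together with the number of genes that the fit with the number as a block called, so this decision was not blind to it. Blocked values are given where they change a call or move a count by more than 1.5 times.

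Each library had 13887672 to 28128186 reads counted to genes, and 3 reads, the floor used for a gene with no reads, correspond to 0.107 to 0.216 CPM. No pair of libraries agreed within counting noise: the chi-square per degree of freedom within groups was 4.59 to 26.2.

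The fit was tested on simulated counts for the 13729 genes with 200 changed genes, using the dispersions estimated per gene. Over 6 simulations of the comparison, 8.39% of genes changed 1.25-fold, 46.6% of those changed 1.5-fold, 82.9% of those changed 2-fold and 95.2% of those changed 4-fold were recovered, with 0 wrong signs. False genes made up 11.1% of the calls without the block, 14.6% with it and 19.2% with DESeq2 1.42.0, all above the nominal 5%. The first 3 simulations, run alone at first, gave 12.7% and 16.5% without and with the block, and the number was raised after these were seen. With dispersions from the fitted trend, 4.54% of the calls were false. Call counts therefore may hold more than 5% false genes. The simulated counts held no effect of the replicate number, and their dispersions came from the fit without the block. The simulations therefore cannot tell which of the fits is more reliable for these libraries.

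The alternatives were other scalings, count filters, tests (DESeq2, limma-voom, earlier edgeR defaults, robust fitting off), thresholds, the replicate block, and leaving out each library. Under these other tests, lists were tested with cameraPR on signed z-scores of the gene p-values. It was run at the same preset correlation, in place of camera on log2 CPM. A changed list call there may come from the change of list test rather than from the tool or option. Further ones were added after seeing the data: leaving out both number 1 libraries, and DESeq2, estimated-correlation and fry runs with the block.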

Results

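The libraries came from DN3 thymocytes of 3 WT and 3 L1 KO samples, and the comparison asks which genes differ when Rpl22l1, a paralog of the ribosomal protein gene Rpl22, is deleted in blood-forming cells. The reads counted to genes were 21571810, 20385508 and 19570475 in WT 1 to 3 and 25657313, 28128186 and 13887672 in KO 1 to 3. Mitochondrial genes took 2.26% to 3.19% of the counts. Xist, expressed from the inactive X chromosome, had 64199 to 132983 reads per library, while Ddx3y, Eif2s3y, Kdm5d and Uty, which lie on the Y chromosome, had 0 reads in all 6 libraries. The number 1 libraries of both groups stood apart from the others: their deviations from the group means correlated at 0.58 across genes, which are not independent replicates.

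Rpl22l1 fell in the L1 KO libraries. Its level was 109 ± 19.95 CPM in WT and 21.6 ± 4.0 CPM in KO (SD, n = 3), which left 19.8% of the WT mean. The 3 WT libraries had 86.3, 123 and 118 CPM, and the 3 KO libraries 18.6, 19.996 and 26.1 CPM, so each library matched the label of its sample. The log2 fold change was −2.35 ± 0.18 (SE), with an adjusted p of 0.00116 in edgeR's quasi-likelihood test. Rpl22l1 (ENSMUSG00000039221) lies on chromosome 3 from 28805436 to 28807424 on the plus strand of GRCm38. Counts cover the whole gene, so reads from any part outside the floxed segment are included. Rpl22, on chromosome 4 from 152325742 to 152334071, had 343 ± 22.5 CPM in WT and 388 ± 28.2 CPM in KO, a log2 fold change of 0.18 ± 0.08. It did not pass the threshold, with an adjusted p of 0.213, but did in the fit with the replicate block, with an adjusted p of 0.0329.

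**Figure D1:**
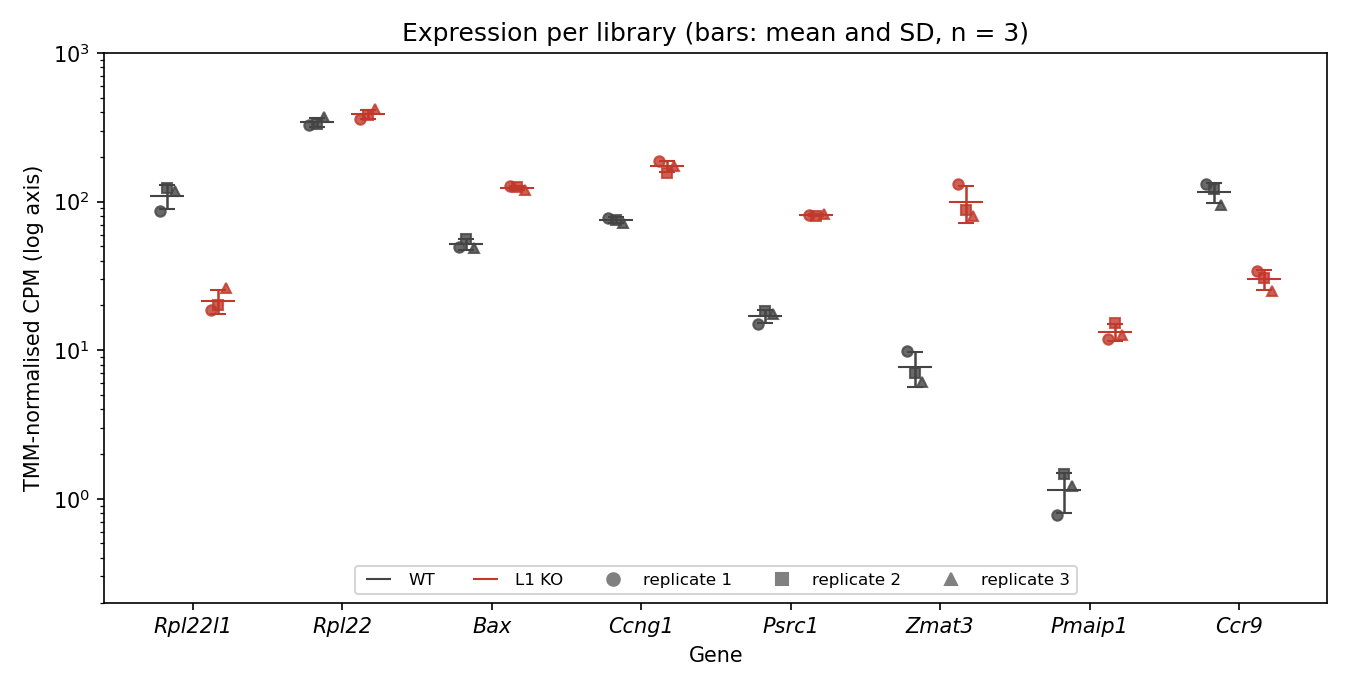
Normalised expression in CPM on a log axis of 8 genes in each library, with WT in grey and L1 KO in red. Horizontal lines are means, whiskers are SD of 3 libraries and marker shapes give the replicate number; Rpl22l1 lies at 18.6 to 26.1 CPM in the KO libraries, below 86.3 to 123 CPM in WT.

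Targets of p53, the transcription factor that acts on DNA damage and other stress, included the 3 largest rises among genes with at least 5 CPM in KO and a symbol that is not a predicted name. Eda2r, a receptor of the tumor necrosis factor receptor family, had 4 reads in the WT libraries together and 771 in KO, a ratio of 179 after scaling for depth with a 95% counting interval of 69.6 to 659. Zmat3, an RNA-binding protein gene, rose from 7.68 ± 1.99 to 99.5 ± 27.2 CPM, a log2 fold change of 3.69 ± 0.27. Pmaip1, which encodes the pro-apoptotic protein Noxa, rose by 3.54 ± 0.21 on the log2 scale. Of 35 tested p53 targets, 20 rose and 1, Sesn1, fell with a log2 fold change of −0.34, and 14 did not pass. Adjusted over the list alone, 20 were higher and 3 lower, as with the block. The list's median log2 fold change was 0.49, and its adjusted p was 1.19e-13 with camera and 0.00152 with fry. With an estimated correlation, under which 0 of the 26 lists passed, its adjusted p was 0.38. Further members that rose were Psrc1 (2.25 ± 0.09), 9030617O03Rik, now named Dglucy (2.78 ± 0.11), and Ptpn14, a phosphatase gene (1.93 ± 0.07). The p53 gene itself, Trp53, was at 236 ± 7.61 and 243 ± 4.14 CPM, with a log2 fold change of 0.04 ± 0.06 and an adjusted p of 0.703. Among members that did not pass, chosen after their values were seen, Cdkn1a, a cell cycle inhibitor, had a log2 fold change of 0.23 ± 0.18, and Mdm2, which encodes the ligase that degrades p53, had 0.08 ± 0.06.

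Of 22 tested apoptosis regulators, 6 rose and 1 fell, with 7 higher and 1 lower adjusted over the list alone. Those that rose include Pmaip1, Bbc3, which encodes Puma (log2 fold change 1.99 ± 0.17), and Bax, which encodes a pore-forming death effector (1.27 ± 0.07, from 51.5 ± 4.30 to 124 ± 4.03 CPM). All 6 that rose are also on the p53 list. Bmf, a BH3-only death gene, fell with a log2 fold change of −1.003 ± 0.108. The list's adjusted p was 0.00888 with camera and 0.00323 with fry, and 0.418 with an estimated correlation. On ranks the camera p was 0.0906.

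All 38 tested genes of G2/M and mitosis had a positive log2 fold change, with a median of 0.43, and 8 passed the threshold. Ect2, a regulator of cytokinesis, had 0.64 ± 0.09, Ndc80, a kinetochore gene, 0.66 ± 0.12, Cdc25b, a phosphatase of mitotic entry, 0.62 ± 0.08, and Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, 0.55 ± 0.10. Adjusted over the list alone, 33 passed, and with the replicate block 33 passed over all genes. Of 37 tested genes of G1/S and DNA replication, 3 rose, among them Mcm3, a helicase subunit gene (log2 fold change 0.32 ± 0.07), and Cdt1, a replication licensing gene (0.30 ± 0.07), with 20 higher and 1 lower adjusted over the list alone and 26 higher and 1 lower with the block. The adjusted camera p was 1.52e-14 for mitosis and 2.77e-08 for replication. Neither list held with an estimated correlation, at an adjusted p = 0.453 and 0.52, or with fry, at an adjusted p of 0.077 and 0.116.

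Of 39 ribosome biogenesis genes, 38 had a positive log2 fold change, with a median of 0.17, and 4 rose: Bysl, Fbl, Utp20 and Gar1, with log2 fold changes of 0.32, 0.32, 0.25 and 0.29. With the block 20 rose, and adjusted over the list alone 10. None of the 33 translation factors passed in edgeR, though all 33 were positive, with a median of 0.16, and 15 passed with the block. None of the 46 tested large-subunit ribosomal proteins passed, with a median of 0.12, and 43 positive; 12 passed with the block. None of the 32 small-subunit ones passed either, with a median of 0.11, 30 positive and 5 passing with the block. In oxidative phosphorylation 0 of 40 passed, with a median of 0.13, and 12 did with the block. In each of these last 4 lists 0 members passed adjusted over the list alone. At an unadjusted p under 0.05 in edgeR, 14 translation factors, 3 large and 2 small ribosomal proteins and 13 oxidative phosphorylation genes passed. DESeq2 called 2, 2, 0 and 1 of them in that order, and limma-voom called 0 in each. Over all 13729 tested genes, 3227 had an unadjusted p under 0.05 in edgeR, and 2684 passed with the block. Both ribosomal protein lists lay below that unadjusted share. The adjusted camera p was 2.77e-08 for ribosome biogenesis, 2.99e-06 for translation factors, 0.000223 for large and 0.00562 for small ribosomal proteins and 5.5e-06 for oxidative phosphorylation. With an estimated correlation the adjusted p of these lists was 0.453, 0.52, 0.682, 0.721 and 0.571 in the same order, and with fry it was 0.077, 0.077, 0.451, 0.491 and 0.133. With the block, fry called translation factors, at an adjusted p of 0.0244. Without WT 1 the camera p was 0.26 for large and 0.465 for small ribosomal proteins, and without KO 2 it was 0.0561 for the small ones.

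Stress and interferon genes gave mixed results. Of 33 tested interferon-stimulated genes, 29 were positive, with a median log2 fold change of 0.63, and 5 rose, including Oas3, an antiviral enzyme (1.01 ± 0.17), Usp18, a negative regulator of interferon signalling (1.04 ± 0.18), and Ifi44 (0.97 ± 0.19). Ifi47, an interferon-inducible GTPase, fell with −0.46 ± 0.09. Adjusted over the list alone 22 were higher and 2 lower, and with the block 24 were higher and 2 lower. The camera p was 2.44e-08, the fry p 0.077, and the adjusted p = 0.453 with an estimated correlation. Of 21 tested genes of the ATF4 integrated stress response, Sesn2 (1.04 ± 0.15), which is also on the p53 list, rose. The amino acid transporter genes Slc7a5 (0.38 ± 0.07) and Slc3a2 (0.41 ± 0.08) rose too. The cystine transporter gene Slc7a11 fell with −1.59 ± 0.36, from a low mean of 1.41 CPM in WT to 0.499 in KO. Adjusted over the ATF4 list alone 8 were higher and 2 lower, as with the block. Its camera p was 0.00245, its fry p 0.077, and the adjusted p = 0.453 with an estimated correlation. Of 28 genes of the unfolded protein response of the endoplasmic reticulum, 1 changed: Xbp1, its transcription factor, fell with −0.53 ± 0.10. That list had a camera p of 0.248. With the block it had 3 higher and 2 lower members, and adjusted over the list alone 0 higher and 1 lower. Of 23 immediate early and heat shock genes, 1, Socs3, fell with −0.66 ± 0.11, the camera p was 0.0802, and 5 were higher and 2 lower with the block, against 0 and 1 adjusted over the list alone. That list passed camera when scaled by library size alone (0.0413), with no count filter (0.0467), and without WT 2 (0.0405), WT 3 (0.00913) or KO 1 (0.0391). It passed cameraPR with robust fitting off (0.0439). With an estimated correlation its adjusted p = 0.609.

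For DN3 identity genes the camera p was 0.858. Of 27 members, 3 rose: Cd2, an adhesion receptor, from 5.03 ± 1.85 to 28.0 ± 4.20 CPM (2.48 ± 0.24), Zap70, a kinase of antigen receptor signalling (0.53 ± 0.10), and Lef1, a transcription factor of early T cells (0.61 ± 0.14). Their median was −0.03 and their mean 0.11, of opposite sign, and with the block 6 were higher and 6 lower. Of 20 beta-selection genes, Cd2, Cd28 and Slc3a2 rose, with a camera p of 0.0802 and 7 higher and 1 lower with the block. Of 17 genes of the double positive stage, 4 fell: Ccr9, a chemokine receptor of thymic homing, from 116 ± 18.6 to 29.9 ± 4.71 CPM (−1.95 ± 0.15), A930013B10Rik (−0.93 ± 0.08), Cd1d1 (−0.49 ± 0.07) and Slc7a11. That list had a camera p of 0.0802, and with the block 6 members were lower. None of 17 Notch targets passed in edgeR, with a camera p of 0.547, and 4 were higher and 3 lower with the block. None of 15 gamma-delta lineage genes passed, with a camera p of 0.973, and 2 were higher and 1 lower with the block. At an unadjusted p under 0.05 edgeR had 7 Notch targets and 1 gamma-delta gene, against 3227 of all 13729 tested genes. DESeq2 called 2 Notch targets and 0 gamma-delta genes, and limma-voom called 0 of either. Adjusted over the list alone, 4 DN3 identity genes were higher and 3 lower, 5 beta-selection genes were higher, 5 double positive genes were lower, and 0 Notch and gamma-delta genes passed. The gamma-delta median was −0.0077 although camera gave the direction as up and fry as down. Camera and the fry p given elsewhere test a shift in 1 direction. Fry's test for change in either direction gave adjusted p of 0.000648 for DN3 identity, 0.00122 for beta-selection and 9.76e-05 for the double positive stage. For Notch targets it gave 0.0109 and for gamma-delta genes 0.587. That test does not weigh a list against the other tested genes. The beta-selection list passed camera when scaled by library size alone (0.0461), with a filter of 5 CPM (0.0374) and without WT 3 (0.00922). It passed cameraPR with DESeq2 (0.00752), limma-voom (0.0401), robust fitting off (0.0485) and DESeq2 with the block (0.00934). With an estimated correlation its adjusted p = 0.592. The double positive list passed camera as lower with a filter of 5 CPM (0.0382) and without WT 2 (0.00852). It passed cameraPR as lower with DESeq2 (0.000121), limma-voom (0.0401), earlier edgeR defaults (0.0377), robust fitting off (0.0367) and DESeq2 with the block (3.74e-06). With an estimated correlation its adjusted p = 0.609.

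Of 8 dendritic markers, Cd74, the class II invariant chain, and H2-Eb1, a class II chain, fell with −1.65 ± 0.28 and −1.88 ± 0.42, from means of 1.52 and 0.674 CPM in WT. The dendritic list was lower with a camera p of 0.0265 and a fry p of 0.0111, and an adjusted p = 0.418 with an estimated correlation. Its camera p was 0.11 on ranks, 0.079 without KO 1 and 0.0718 without both number 1 libraries. Its cameraPR p was 0.0935 with DESeq2 and 0.149 with DESeq2 and the block. The 6 erythroid and platelet genes had a median of −1.04 and none passed, though the camera p was 0.0203. The 4 of them with the smallest p had low means, of 0.775 to 3.72 CPM in WT and 0.282 to 0.968 in KO. Among these, Hba-a2 had 38, 37 and 20 reads in WT 1 to 3 and 18, 4 and 0 in KO 1 to 3. That list had a cameraPR p of 0.0558 with earlier edgeR defaults, a fry p of 0.077 and an adjusted p = 0.453 with an estimated correlation. Of 11 mature T markers, 2 rose: Klf2, a factor of T cell exit (1.80 ± 0.21, from 1.03 to 3.60 CPM), and Cd6 (0.45 ± 0.09). That list had a camera p of 0.00888, a fry p of 0.0193 and an adjusted p = 0.418 with an estimated correlation. Its camera p was 0.218 with a filter of 5 CPM, its cameraPR p 0.0809 with DESeq2 and the block, and its fry p 0.0638 with the block. Of 10 progenitor markers, Bcl11a and Kit, genes of early progenitors, fell with −1.12 ± 0.13 and −0.72 ± 0.13, with a camera p of 0.39. Fry's test for change in either direction gave the progenitor list an adjusted p of 9.76e-05. Of 8 epithelial and stromal markers, Epcam fell (−0.75 ± 0.11) and Pdgfrb rose (0.67 ± 0.15), with a camera p of 0.16 and a fry p of 0.0379, or 0.377 with the block, and an adjusted p = 0.453 with an estimated correlation. None of the 5 B lineage, 7 myeloid and 5 NK and innate lymphoid markers passed, with camera p of 0.837, 0.837 and 0.511; with the block 1 B lineage marker was lower and 2 NK markers were higher. At an unadjusted p under 0.05 edgeR had 2 B lineage, 0 myeloid, 1 NK and 2 erythroid and platelet markers, against 3227 of all 13729 tested genes. In the same order of lists DESeq2 called 2, 0, 1 and 2, and limma-voom called 0 in each list. Adjusted over the list alone, 4 dendritic, 3 progenitor and 1 erythroid and platelet marker were lower, 3 mature T markers were higher and 1 lower, 1 stromal marker was higher and 2 lower, 1 B lineage marker was higher and 1 lower, and 0 myeloid and NK markers passed. With the block 4 dendritic and 1 erythroid and platelet marker were lower, 3 mature T markers were higher and 1 lower, 1 progenitor marker was higher and 3 lower, and 1 stromal marker was higher and 2 lower. The myeloid median was −0.0034 although camera gave its direction as up.

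**Figure D2:**
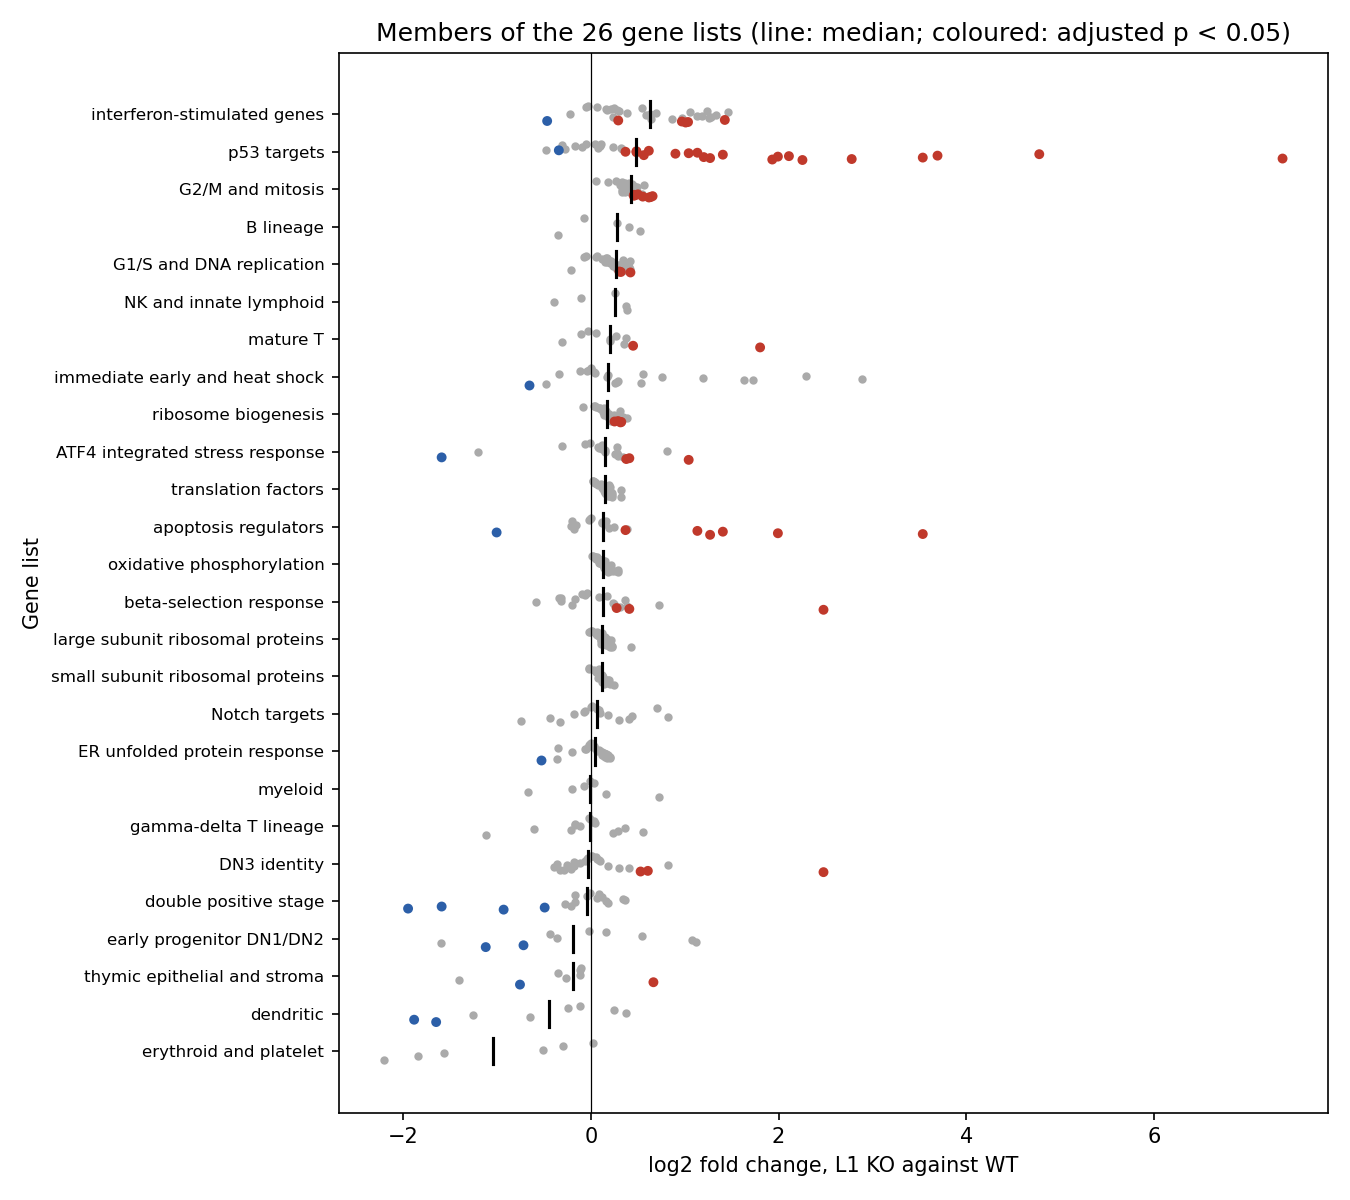
Log2 fold change (L1 KO against WT) of each tested member of the 26 fixed lists, with red and blue for members past the adjusted threshold that rose and fell and grey for the rest. The black line is the median of each list, which reaches 0.63 for interferon-stimulated genes, 0.49 for p53 targets and −1.04 for erythroid and platelet genes. Only 6 erythroid and platelet genes were tested, and the 4 with the smallest p had WT means of 0.775 to 3.72 CPM.

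Further large rises were Tnfsf8, the gene of CD30 ligand (2.43 ± 0.16), Zfp365 (2.43 ± 0.13), Ifi204 (2.30 ± 0.35), Phlda3, a p53 target (2.11 ± 0.20), and Serpine2, a protease inhibitor gene (2.08 ± 0.17). Among genes with at least 5 CPM in WT and a symbol that is not a predicted name, the largest falls after Rpl22l1 and Ccr9 were Kcnh3, a potassium channel gene (−1.90 ± 0.17), Grm4, a glutamate receptor gene (−1.87 ± 0.14), Adam11 (−1.81 ± 0.14), Plxnb2, a semaphorin receptor gene (−1.78 ± 0.20), Krt83 (−1.59 ± 0.16), Olfr1507 (−1.37 ± 0.19), Nat8l (−1.36 ± 0.30) and Tdrd5 (−1.31 ± 0.16). Smad1 and Smad2 had log2 fold changes of 0.02 ± 0.09 and 0.01 ± 0.07, with adjusted p of 0.928 and 0.939.

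Of 13729 genes tested, 286 were higher and 340 lower in KO, 626 together, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. All 626 had non-overlapping groups, as had 28.4% of all tested genes, against 10% by chance. With the replicate block 1306 were higher and 1378 lower, and 624 of the 626 were called in both fits with the same direction. The count rested on single libraries: it was 415 without WT 1, 102 without WT 2, 255 without WT 3, 2043 without KO 1, 160 without KO 2 and 198 without KO 3. Without both number 1 libraries, an alternative added after seeing the data, it was 2798. Of the 59 named genes past the threshold, 27 stayed past it without WT 2 and 58 without KO 1. The p53 members that rose numbered 13 without WT 2.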

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

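The replicate block, the test, the thresholds and single libraries moved the number of changed genes; the cause was not tested except where stated. With the replicate block 2684 genes were called, 1306 higher and 1378 lower. DESeq2 called 1222, with 612 higher and 610 lower. An adjusted p under 0.1 gave 1510 (688 and 822). An adjusted p under 0.05 with a change of at least 2-fold gave 160 (84 and 76). These limits are looser and stricter by construction. Chosen after seeing the data, leaving out both number 1 libraries gave 2798 (1391 and 1407), and DESeq2 with the replicate block gave 1707 (916 and 791). Leaving out each library in turn gave 102 to 2043 genes, 54 to 1049 higher and 48 to 994 lower, with the fewest without WT 2 and the most without KO 1; 13 to 20 p53 members rose. Rpl22l1 stayed lower under every alternative run, from −2.50 to −2.25 on leaving out libraries.

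Of the 26 lists, 14 passed camera, 0 with an estimated correlation (p53 targets: adjusted p = 0.38) and 5 with fry. With the replicate block, 0 passed with an estimated correlation (p53 targets: adjusted p = 0.478) and 4 with fry, both chosen after seeing the data. Leaving out each library gave 12 to 16. With the block, fry gained translation factors (adjusted p 0.0244) and lost mature T (0.0638) and stroma (0.377); blocked camera in edgeR passed the same 14 lists. In cameraPR on the DESeq2 results the block ended the mature T call (0.0285 to 0.0809). Of the 59 named genes past the threshold, 0 changed direction under any alternative, and the block kept all 59 and added 40 of the other 61.

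Values that changed sign were all short of the threshold. Smad2 was at −0.0200 with library size alone, −0.000835 with a 5 CPM filter, and −0.0149 (without KO 3) to 0.0559 (without KO 1) on leaving out libraries. Smad1 was at −0.0132 with library size alone and −0.0199 (without WT 2) to 0.0870 (without WT 1) on leaving out libraries. Aire was at 0.0158 without both number 1 libraries. The gamma-delta list turned lower with adjusted p of 0.703 (no count filter), 0.847 (fry) and 0.931 (without number 1), the myeloid list with 0.764 (no count filter) and 0.995 (DESeq2 with the block), the DN3 list with 0.974 (ranks) and the B lineage list with 0.866 (fry with the block). On leaving out libraries, some of which turned them lower, the adjusted p ranged from 0.742 to 0.974 for gamma-delta, 0.418 to 0.962 for myeloid and 0.465 to 0.97 for DN3 identity. Depth limits genes near 0.107 to 0.216 CPM, the level of 3 reads.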

Other observations

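The tests of inherited segments in the number 1 libraries, of clock genes and of the neighbours of Rpl22l1 were chosen after related results were seen, and so were the genes named in this part. Tnfsf4, the gene of OX40 ligand, rose from 0.129 ± 0.102 to 3.19 ± 0.176 CPM, with 1 to 5 reads in each WT library. Cd81, a tetraspanin gene, rose by 2.08 ± 0.11 on the log2 scale and Ptp4a3, a phosphatase gene, by 1.13 ± 0.08. H2-T10, a nonclassical class I gene with close relatives whose reads may be shared, had 1.46 ± 0.11. Lsp1, a leukocyte cytoskeleton gene, had −1.04 ± 0.08, and Spo11, the gene of the meiotic break enzyme, had −0.99 ± 0.07, from 93.7 ± 0.992 to 47.3 ± 2.63 CPM.

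Of 35 tested p53 targets 20 were higher in KO, 1 was lower and 14 did not pass. With an estimated correlation the list did not pass (adjusted p = 0.38, or 0.478 with the block), nor did any other of the 26 lists. All 20 raised members were also called higher with the replicate block. With mitotic expression as a covariate, 14 of the 20 raised members stayed past the threshold, with a median log2 fold change of the 20 of 1.34 before and 1.41 after, although the genes past it over all tested genes went from 626 to 73. Of the 21 called p53 members, 52.4% had another called gene within 1 Mb, against a median of 52.4% in 10000 random draws. The central 95% of these draws reached 76.2%, so only a large excess could have shown, and background segments are not excluded for these genes. Over all called genes the mean number of called neighbours was 1.42, above 1.30, the upper end of the central 95% of random draws. Segments therefore stay open for other calls too. The deletion of Rpl22l1 stays open as an explanation, and no test here bears on a mechanism. All KO libraries came from mice with Cre and all WT libraries from mice without it. An effect of Cre itself therefore cannot be told apart from the loss of Rpl22l1.

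The number 1 libraries of both groups differed together from numbers 2 and 3, in 1951 genes, with 1004 higher and 947 lower, of which 40 were also called between the groups. As a set these genes showed no excess of neighbours, which shared segments of the mixed background would give. The 1880 with a position had a mean of 3.13 others within 1 Mb. Random draws had a median of 3.44, and 3.70 was the upper end of their central 95%. A few segments holding a small part of the genes would not show in this mean and stay open. A first version of that test, the share with any such neighbour (84.3%), was set aside because chance alone gave 84.6%. The correlation of 0.580 stayed at 0.581 after GC content and length trends were removed, and 0 of 6 tested clock genes of the phase opposite to Arntl (1.47) passed the threshold in the opposite direction, with log2 differences from −0.38 for Per3 (adjusted p 0.0601) to 0.18 for Tef. The mitochondrial genome was the only chromosome past the threshold in Fisher's exact test, with 12 of 21 genes differing (57.1%, adjusted p 0.000136). The mitochondrial share was the lowest of each group in number 1 (2.52% and 2.26%). Fisher's test counts genes as independent, but mitochondrial genes move together with this share, so its p may overstate the evidence. Of the immediate early and heat shock genes looked at, Fosb had −4.62 (adjusted p 0.000548). Jun, Junb, Dusp1 and Hspa1b had −1.22, −1.20, −0.94 and −0.66 without passing (adjusted p 0.271, 0.342, 0.243 and 0.613). The design gives no group for the numbers, and differences in handling, RNA quality or batch were not tested and stay open.

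Eif5a2 ends 6.59 kb before Rpl22l1 on the same strand, on chromosome 3 from 28781276 to 28798846, and rose from 5.23 ± 0.791 to 9.87 ± 0.358 CPM (0.91 ± 0.14, adjusted p 0.0108 in edgeR). Of the other 13 tested genes within 3 Mb, 1, Ect2, passed, or 7.69% with an exact binomial upper limit of 36.0%, against 4.56% of all genes. With the replicate block Prkci passed too (adjusted p 0.0228, against 0.0611 without it), which makes 2 of 13, against 2684 of all 13729 tested genes in that fit. Mice of both groups carried the floxed gene, so a segment linked to it would be shared where their floxed copies are equal in number. The values here still cannot tell a segment that differs between the groups from a regional effect of the deleted allele. The neighbours are few and no coverage along the genes was analysed here.

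Of the 10 splits of the 6 libraries into groups of 3, 1, the real one, gave as many as 626 genes, and the highest other gave 2. The splits are too few for a share under 0.05. Of the 4 splits that part all 3 same-numbered pairs, the real one included, the other 3 gave 0 genes each.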
